A study of Caenorhabditis elegans with 10 samples.

How the data were processed

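Polyadenylated RNA from whole Caenorhabditis elegans was sequenced as stranded libraries, per the labels' protocols. The worms were collected around the last larval stage and before adulthood, with about 3000 worms per sample and an RNA integrity number above 8.0. There were 5 genotypes: the wild type N2, math-33(tm3561), daf-2(e1370), daf-2(e1370);math-33(tm3561) and daf-16(mu86);daf-2(e1370). Each genotype was either kept at 15 °C or moved to 25 °C late in larval life for 22 hr. This gave 10 libraries with 1 library per group, so a difference between 2 libraries has no replicate check and no p-value was computed for it.

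The deposited table gives FPKM (fragments per kilobase per M reads) for 47467 transcripts in the 10 libraries. STAR, HOMER, edgeR and the genome build ce10 are named in the submitters' processing notes; the role and version of each are not given in the sources used here. Coordinates are those of the deposited table. Of its transcripts, 1104 carry no gene name. They held between 1.723 and 1.974% of the summed FPKM of a library and were left out of all tests. The other transcripts belong to 40857 gene symbols, of which 40446 (99.0%) matched a locus of the RefSeq gene table of assembly WBcel235, used here only for current names and for which genes neighbour each other. Where a symbol had several transcripts (3457 symbols), the one with the highest mean FPKM stood for the gene. How the authors assigned reads shared by overlapping or near-identical genes is not given in the sources used here. Values of paralogs (msp, ssp, nspd, pud, col and vit families) and of overlapping genes are therefore uncertain, and counts of such genes may not be of separate observations.

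Sequencing depth was recovered from the FPKM values. In transcripts of 300 to 1500 bases, low FPKM values multiplied by length were whole multiples of 1 step per library. In every library 100.0% of these values came out whole within the rounding of the table plus a tolerance of 0.01%. The step gives between 25.21 and 35.22 M reads per library. Even read numbers outnumbered odd ones by 2.595 to 3.262 times, as when both mates of a pair are counted, so counting intervals used pairs (12.61 to 17.61 M per library). Intervals of folds are exact 95% intervals for a ratio of 2 counts, and a gene at 0 has a floor of 3 counts, which is 0.17 to 0.238 FPKM for a transcript of 1000 bases. Intervals and floors cover counting error only. No count model was fitted for the comparisons, because the table holds FPKM. Binomial tests on the recovered pairs were used only for the question of shallower sequencing of the math-33 libraries.

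Values were analysed as log2(FPKM + 1), a scale that understates the change of weakly expressed genes. Genes with at least 1 FPKM in at least 2 libraries were kept (16085 genes). Of these, 1379 have transcripts under 200 bases and 629 are 21ur genes, whose small RNAs of the piRNA class have entries of 20 bases in the table. Such entries rest on few reads and occupy many places among the largest differences. Some overlap and have equal values, so the same reads can stand in several places. The libraries hold polyadenylated RNA, so values of 21ur entries are not taken as levels of piRNAs. Differences between 2 libraries were counted at 1 log2 unit. A linear model with genotype and temperature terms was fitted to the 10 libraries with limma and a mean-variance trend, leaving 4 residual degrees of freedom. It treats the temperature response as shared by all genotypes, so genotype-specific responses to temperature enter its error. Its contrasts were the temperature effect, 4 genotype differences, the effect of math-33 loss over both backgrounds and the interaction of math-33 with daf-2. P-values were adjusted by the Benjamini-Hochberg method at 0.05. The fitted spread is between genotypes and temperatures, not between replicate cultures. Leaving out 1 library leaves its genotype with 1 library, which then adds nothing to the fitted spread. Counts of genes passing can change for that reason alone.

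The 24 gene lists, the named-gene rule, the tests and the alternatives were fixed before the data were examined, except where a later choice is named. The lists were DAF-16 activated targets, DAF-16 repressed genes, the insulin/IGF pathway, heat-shock proteins, the unfolded protein responses of the endoplasmic reticulum and of mitochondria, antioxidant enzymes, carbohydrate metabolism (glyoxylate cycle, gluconeogenesis and glycolysis), fat metabolism, innate immunity, xenobiotic detoxification, proteasome subunits, deubiquitylating enzymes, ribosomal proteins, vitellogenins, oocyte and eggshell genes, germline proliferation and meiosis, sperm, adult cuticle, molting and larval collagens, muscle, intestine, neurons and dauer-enriched genes. Some genes stand in several lists. Of the 43 DAF-16 activated targets listed, 38 passed the expression filter, and of the 22 repressed genes 18 did. A list's median difference between 2 libraries was placed among 10000 random lists of the same size matched on mean expression, which describes those libraries and is not a test of the conditions. For the limma contrasts, 168 set tests (24 lists by 7 contrasts) were run with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. At the preset correlation 80 tests had an adjusted p under 0.05, with an estimated correlation 0 did, and with fry 0 did.

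Genes named are math-33, daf-16 and daf-2 in every library; the 8 genes with the largest positive and the 8 with the largest negative difference at 25 °C in each of 4 comparisons, among genes with the same sign at 15 °C; the 5 with the largest change in each direction among those past the threshold of each limma contrast; up to 2 members in each direction of each list discussed; and sod-3, mtl-1, dod-3, hsp-12.6, lys-7, ins-7 and dod-17 in every library. Where 21ur genes took places under this rule, the text gives their number with an example, and genes from transcripts of at least 200 bases are named instead, a choice made after the values were seen.

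On simulated data with the design and gene means of these libraries (16085 genes), the model recovered 86.6, 100 and 100% of genes changed 2-, 4- and 8-fold by temperature, 52.2, 97 and 98.5% of those changed in daf-2;math-33 against daf-2, 44.8, 92.5 and 97% of those changed in daf-2 against daf-16;daf-2, and 91, 98.5 and 100% of those changed by math-33 loss. The simulation assumed a temperature response shared by the genotypes. Changes were planted only in well expressed genes, and genotype changes were equal at both temperatures. The shares therefore do not hold for weakly expressed genes or for changes that differ between temperatures. Alternatives were other pseudocounts (0.1 and 5), other filters, thresholds of 1.5-fold and 2 log2 units, centring each library, quantile normalization, every transcript separately, a model without the trend, a robust model, a term for a temperature response of the daf-2(e1370) strains, a model of 8 libraries with background and temperature as blocks, and leaving out each library in turn. Transcripts of at least 200 bases alone and the residuals after a regression on temperature differences were added after the data were seen. The computations used R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.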

Results

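Messenger RNA was measured in whole nematodes of 5 genotypes at 2 temperatures, with 1 library for each of the 10 groups. DAF-2 is the insulin/IGF-1 receptor, whose partial loss in daf-2(e1370) at 25 °C lets the FOXO transcription factor DAF-16 act in the nucleus, and MATH-33 is a deubiquitylating enzyme. The main question was how DAF-16 target genes are expressed in daf-2 with and without math-33. The daf-16;daf-2 strain shows expression without DAF-16, and the math-33 single mutant against N2 compares strains that differ in math-33 with an intact receptor. Depth at 15 and 25 °C was 31.79 and 27.73 M reads in N2, 25.21 and 31.24 in math-33, 35.22 and 31.16 in daf-2, 28.12 and 27.55 in daf-2;math-33, and 25.39 and 29.69 in daf-16;daf-2. Values are FPKM, differences are on the log2(FPKM + 1) scale, and folds between 2 libraries carry 95% counting intervals, which hold no variation between cultures. With 1 library per group, differences between 2 libraries have no replicate check and no p-value.

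The targeted genes were read first in every library. The math-33 transcript (chromosome V, 11114026 to 11118135) stood at 78.5 and 79.3 FPKM in N2, 71.3 and 59.8 in daf-2, and 77.6 and 69.3 in daf-16;daf-2 at 15 and 25 °C. It stood at 15.9 and 14.1 FPKM in math-33 and at 14.4 and 13.9 in daf-2;math-33. At 25 °C this was 5.62-fold lower than N2 (interval 5.20 to 6.09) and 4.29-fold lower than daf-2 (3.94 to 4.68). The short 3' transcript of daf-16 (chromosome I, 10772988 to 10775039) was at 182 and 164 FPKM in daf-16;daf-2 against 81.3 to 135 FPKM in the other 8 libraries, and it does not test the deletion. The 7 longer daf-16 transcripts do. Reads beyond the short transcript numbered 0 in both daf-16;daf-2 libraries for 4 of them, which held 188 to 356, 195 to 362, 87 to 150 and 2 to 18 reads elsewhere. Of the other 3, 2 held 22 to 23 and 62 to 123 reads in daf-16;daf-2 against 168 to 385 and 204 to 416 elsewhere, and the last held 0.315 to 0.640 reads per M reads of the library against 5.05 to 9.47 elsewhere. The daf-16 short transcript was at 135 and 130 FPKM in daf-2 and at 81.3 and 95.02 in daf-2;math-33. The daf-2 transcript ranged from 20.5 to 43.3 FPKM and cannot test e1370, a point mutation.

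**Figure D1:**
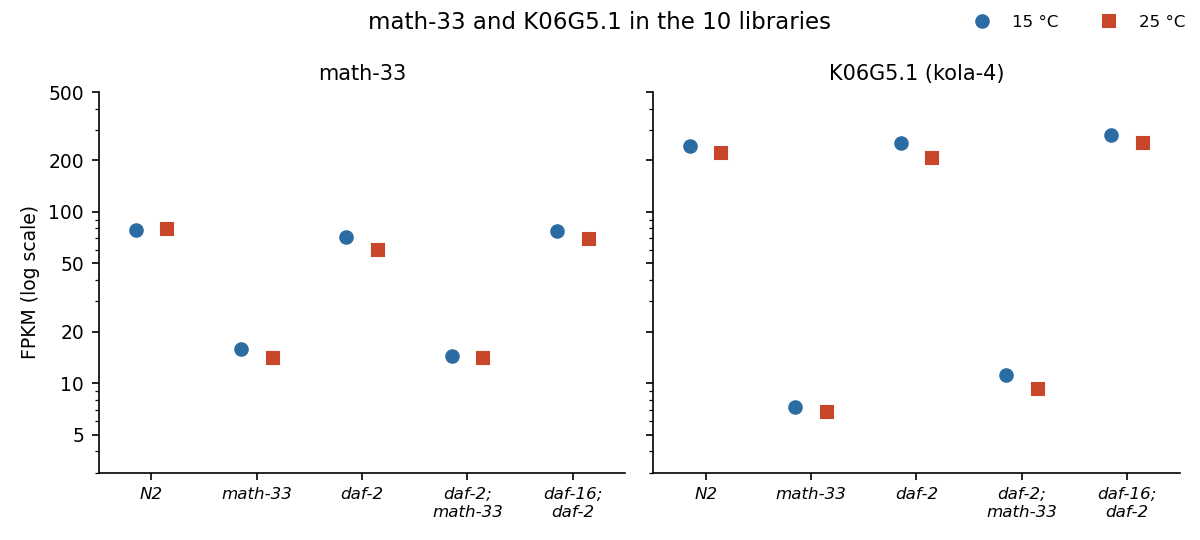
FPKM (log scale) of math-33 and of K06G5.1 in each of the 10 libraries, with 1 point per library, circles for 15 °C and squares for 25 °C. Both genes are lower in the 4 libraries that carry math-33(tm3561), math-33 at 13.9 to 15.9 FPKM and K06G5.1 at 6.82 to 11.16 FPKM.

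The comparison of daf-2 with daf-16;daf-2 asks which genes depend on DAF-16 when the receptor is impaired. At 25 °C sod-3, the manganese superoxide dismutase, was 30.5-fold higher in daf-2 (153 against 5.02 FPKM, interval 22.9 to 41.5), and mtl-1, a metallothionein, was 205.6-fold higher (553.9 against 2.69 FPKM, 108.1 to 450.3). The lysozyme gene lys-7 was 11.97-fold higher (10.9 to 13.2) and dod-3 121.5-fold higher (21.4 to 4836). Among the largest differences were hsp-12.3, a small heat-shock protein (180.4 against 2.16 FPKM), the ferritin gene ftn-1 (221.3 against 4.04), the noncoding RNA tts-1 (4248 against 87.03), the lectin gene clec-61 (71.0 against 0.503), F21C10.11 (117.3 against 1.12), F17B5.1 (40.9 against 0.101) and F21F3.3, now icmt-1 (116.7 against 3.43). At 15 °C the folds were 7.79 for sod-3 (4.80 to 13.4), 8.89 for mtl-1 (2.82 to 45.1) and 2.86 for lys-7 (2.62 to 3.13). For dod-3 it was 0.43 (0.536 against 1.24 FPKM), with an interval of 0.067 to 2.22 that includes no difference. In the other direction dod-17 was 9.54-fold lower in daf-2 at 25 °C (7.39 to 12.5), irg-5, an infection response gene named F35E12.5 in the table, stood at 17.5 against 1003 FPKM, F55G11.2 at 1.33 against 42.4 and C36C5.15 at 0.264 against 16.8. The other 5 of the 8 genes with the largest decreases were 21ur genes, short entries that rest on few reads, such as 21ur-11650 (0 against 25.3 FPKM). The transcript of hsp-12.6 reached 2.63 FPKM in daf-2 at 25 °C, was at most 0.582 elsewhere and did not pass the expression filter. The insulin gene ins-7 ranged from 0 to 4.07 FPKM, the highest value being in math-33 at 25 °C.

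Of the 38 DAF-16 activated targets, 27 were at least 1 log2 unit higher in daf-2 than in daf-16;daf-2 at 25 °C and 0 lower, with a median of 1.37 (random lists -0.20 to 0.15); mtl-2 (26.3 against 48.6 FPKM) and old-1 (0.92 against 2.54) were lower. At 15 °C the median was 0.25, 9 were higher and 2 lower. The 18 repressed genes had medians of -0.94 at 25 °C (0 higher, 9 lower) and -0.44 at 15 °C (0 higher, 5 lower), with dod-22 at 1.08 against 22.5 FPKM at 25 °C. Dauer-enriched genes had a median of 1.38 at 25 °C, with 15 of 22 higher. Of the stress and metabolic lists at 25 °C, antioxidant enzymes had a median of 0.51 (6 of 20 higher, 1 lower), carbohydrate metabolism 0.33 (pck-1, 340.5 against 125.8 FPKM) and fat metabolism 0.30 (the desaturase gene fat-5, 371.1 against 49.9 FPKM). Innate immunity genes went both ways, 11 higher and 12 lower, with spp-2 at 622.7 against 32.4 FPKM and clec-4 at 0.731 against 15.4. Heat-shock proteins had a median of -0.10 and a mean of 0.47, and intestinal genes a median of -0.23 and a mean of 0.02. The proteasome list had a median of -0.29 and ribosomal proteins -0.31. The stage-linked lists also differed: molting and larval collagens had medians of -0.34 at 25 °C and -0.82 at 15 °C, and vitellogenins, the yolk proteins, -1.07 at 25 °C.

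In the limma contrast over both temperatures, 5 genes rose in daf-2 and 1 fell (1964 genes at an unadjusted p under 0.05). F21C10.11 rose by 5.24 (SE 0.31, limma adjusted p = 0.00829), F17B5.1 by 4.57 (SE 0.36, adjusted p = 0.0267), lea-1, a dauer-linked LEA protein gene, by 3.72 (SE 0.31, adjusted p = 0.0267), the small heat-shock gene sip-1 by 3.46 (SE 0.30, adjusted p = 0.0267) and F43D9.8 by 3.23 (SE 0.30, adjusted p = 0.0373). The 146-base F43D9.8 transcript overlaps sip-1. The 20-base entry 21ur-11650 fell by 4.197 (SE 0.41, adjusted p = 0.0464), which is not a measure of a piRNA. Of the DAF-16 activated targets 1 rose, lea-1, and 11 rose when adjusted over the list alone; of the repressed genes 0 fell, and 6 fell when adjusted over the list alone. Camera placed the activated list above other genes (adjusted p = 2.1e-09) and the repressed list below (1.78e-08), with adjusted p = 0.56 with an estimated correlation for both. Of the dauer-enriched genes 2 rose, lea-1 and sip-1, and 7 rose when adjusted over the list alone. Without an expression filter 1 gene was higher and 3 were lower. The count of 6 genes rested on single libraries: it was 169 without daf-2 at 15 °C, 2 without daf-2 at 25 °C or either math-33 library, and 0 without any of the N2, daf-2;math-33 or daf-16;daf-2 libraries. Across genes, the differences at 25 and 15 °C had r = 0.072 and rho = 0.167, and 180 genes were higher at both temperatures (47.1 from independent lists) and 161 lower (44.5), of which 46 and 78 have transcripts under 200 bases.

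**Figure D2:**
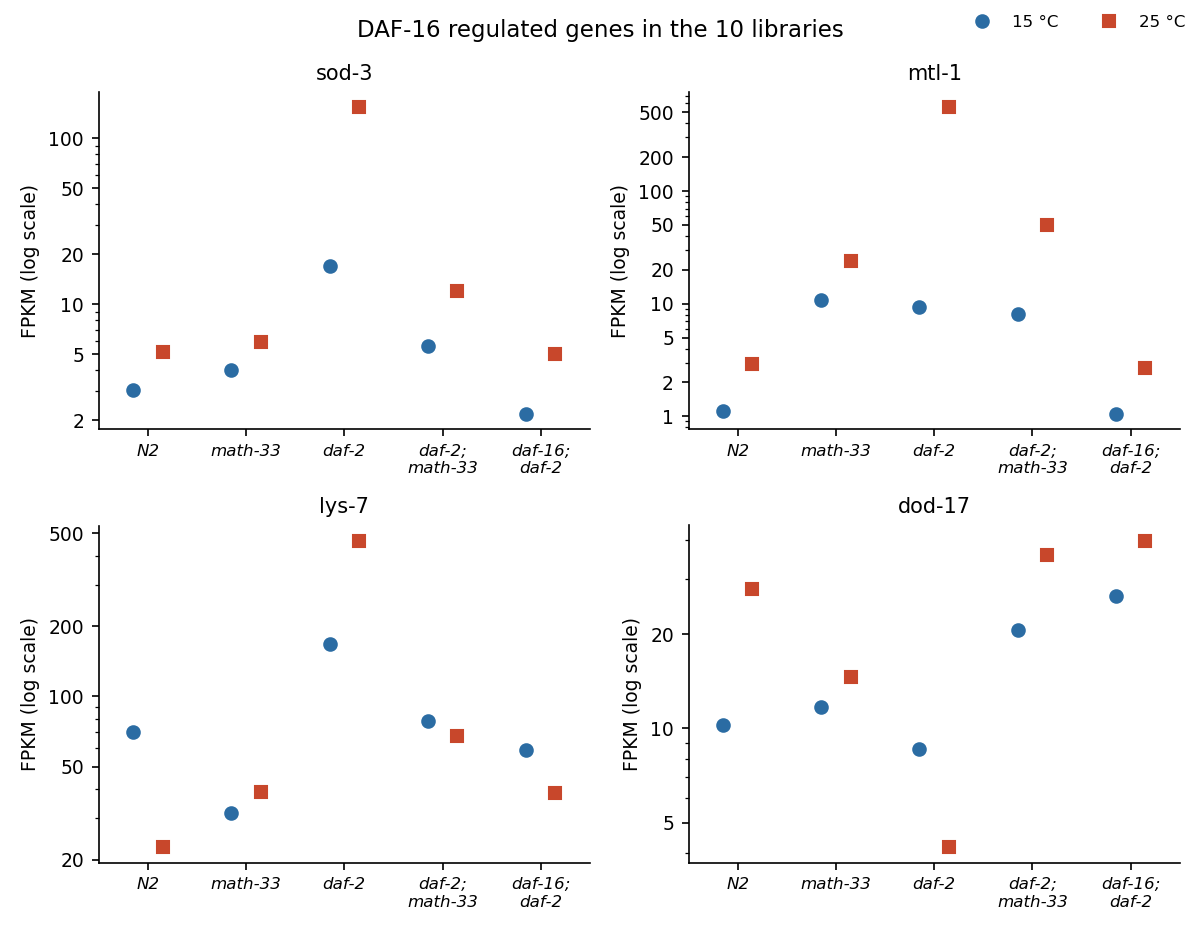
FPKM (log scale) of sod-3, mtl-1, lys-7 and dod-17 in each of the 10 libraries, with 1 point per library, circles for 15 °C and squares for 25 °C. In daf-2 at 25 °C sod-3, mtl-1 and lys-7 reach 153, 553.9 and 463.1 FPKM, and dod-17 is at 4.17 FPKM.

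The comparison of daf-2;math-33 with daf-2 asks what math-33 loss does to these genes when DAF-16 is active. At 25 °C sod-3 was 12.83-fold lower in daf-2;math-33 (11.9 against 153 FPKM, interval 10.6 to 15.8), mtl-1 11.01-fold lower (50.3 against 553.9 FPKM, 9.35 to 13.04), dod-3 22.6-fold lower (9.41 to 70.6) and lys-7 6.87-fold lower (6.37 to 7.41), while dod-17 was 8.60-fold higher (6.65 to 11.3). At 15 °C sod-3 was 3.05-fold lower (2.23 to 4.23), lys-7 2.14-fold lower (1.98 to 2.31) and dod-17 2.39-fold higher (1.96 to 2.92). At that temperature mtl-1 was 1.16-fold lower and dod-3 1.67-fold higher (0.895 against 0.536 FPKM), both with intervals that include no difference. In daf-2;math-33 at 25 °C sod-3 was above the 5.02 FPKM of daf-16;daf-2, and mtl-1 above its 2.69 FPKM. Among the genes with the largest differences hsp-12.3 was at 3.995 against 180.4 FPKM, ftn-1 at 13.8 against 221.3, F15B9.6 at 1.3 against 28.97, pud-4, named F15E11.12 in the table, at 49.4 against 609.7, and K06G5.1 at 9.30 against 206.9. The other 3 of the 8 were 21ur genes, such as 21ur-2020 (1.82 against 142.8 FPKM). On the other side, msp-10, a major sperm protein gene, was 23.03-fold higher in daf-2;math-33 (69.6 against 3.02 FPKM, 14.4 to 39.3), and 7 of the 8 were 21ur genes, such as 21ur-14510 (50.8 FPKM against 0). Among longer transcripts, ssp-19, a sperm-specific family gene, was at 39.3 against 2.35 FPKM and F55G11.2 at 27.6 against 1.33.

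Of the DAF-16 activated targets, 19 of 38 were at least 1 log2 unit lower in daf-2;math-33 at 25 °C and 1 was higher (median -1.05, random lists -0.12 to 0.23). The heat-shock gene hsp-16.41 (2.88 against 0.748 FPKM) and mtl-2 (52.4 against 26.3) went the other way. At 15 °C the median was -0.19 (random lists -0.05 to 0.23), with 3 lower and 2 higher. Of the 18 repressed genes 10 were higher at 25 °C and 0 lower (median 1.09), led by dod-22 (15.0 against 1.08 FPKM), and 5 were higher at 15 °C (median 0.41). Dauer-enriched genes had a median of -0.92 at 25 °C, with 7 lower, and 0.27 at 15 °C. Antioxidant enzymes had a median of -0.31 at 25 °C, carbohydrate metabolism -0.37 (pck-1, 140.6 against 340.5 FPKM) and fat metabolism -0.31, with lipl-2, a lysosomal lipase gene, at 43.5 against 169.7 FPKM and fat-5 at 91.2 against 371.1. The insulin/IGF pathway had a median of -0.21, and heat-shock proteins -0.02 with 3 of 18 lower and 1 higher. Sperm genes moved with the genotype as well: 46 of 54 were higher in daf-2;math-33 at 25 °C (median 2.03) and 43 at 15 °C (median 1.56). The 5 vitellogenins had medians of 1.17 and 0.86, and molting and larval collagens -0.31 and 0.44.

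The limma contrast over both temperatures called 2 genes, both lower (2415 at an unadjusted p under 0.05). K06G5.1, now kola-4 (chromosome X, 14214905 to 14218914), fell by 4.36 (SE 0.12, adjusted p = 3.98e-05) and math-33 fell by 2.13 (SE 0.13, adjusted p = 0.00553). Of the DAF-16 activated targets 0 passed and 1 fell when adjusted over the list alone; of the repressed genes 0 passed and 7 rose when adjusted over the list alone. Camera gave the activated list an adjusted p of 6.22e-08 for lower and the repressed list 1.38e-05 for higher, with adjusted p = 0.56 with an estimated correlation for both. The count of 2 became 160 (147 higher, 13 lower) and 140 (128 higher, 12 lower) without N2 at 15 and 25 °C, 109 (59 higher, 50 lower) and 22 (19 higher, 3 lower) without daf-2 at 15 and 25 °C, and 1 without either daf-2;math-33 library. After centring 6 genes were higher and 6 lower, with a filter of 5 FPKM 11 and 7, and among transcripts of at least 200 bases 12 and 6. At 25 °C 1764 genes were at least 1 log2 unit higher and 825 lower, and at 15 °C 1416 and 317; after quantile normalization the share of higher genes was 56.3 in place of 68.1% and 59.6 in place of 81.7%. The median of all genes at 15 °C was 0.10.

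Both comparisons share the daf-2 library of each temperature, so an opposite difference in the 2 can come from that library. DAF-16 dependent genes were therefore picked at 1 temperature and read at the other. The 667 genes at least 1 log2 unit higher in daf-2 than in daf-16;daf-2 at 15 °C had a median of -0.29 in daf-2;math-33 against daf-2 at 25 °C (random lists 0.01 to 0.11), with 155 (23.2%) at least 1 log2 unit lower and 72 (10.8%) higher. Their median in daf-2 against daf-16;daf-2 at 25 °C was 0.36. Of these genes 180 were also higher in daf-2 at 25 °C; 123 of the 180 were lower in daf-2;math-33 and 2 higher, but this smaller group was chosen on the same daf-2 library. The 1136 genes picked at 25 °C had a median of 0.03 at 15 °C, below random lists (0.12 to 0.18), with 7.4% lower and 16.37% higher, and with the sign turned to -0.08 after centring and -0.09 after quantile normalization. The 873 genes lower in daf-2 at 15 °C had a median of 0.22 at 25 °C (random lists 0.02 to 0.12; 21.1% higher, 8.8% lower), and the 819 picked at 25 °C had 0.28 at 15 °C (0.12 to 0.20; 23.6% higher, 6.8% lower). Among genes picked at 2 log2 units at 15 °C the median was 0.0, at percentile 2.6 of random lists and so inside their central 95%. For genes picked at 1 log2 unit at 15 °C, the median at 25 °C was -0.014 at a pseudocount of 0.1 and -0.12 without a filter.

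**Figure D3:**
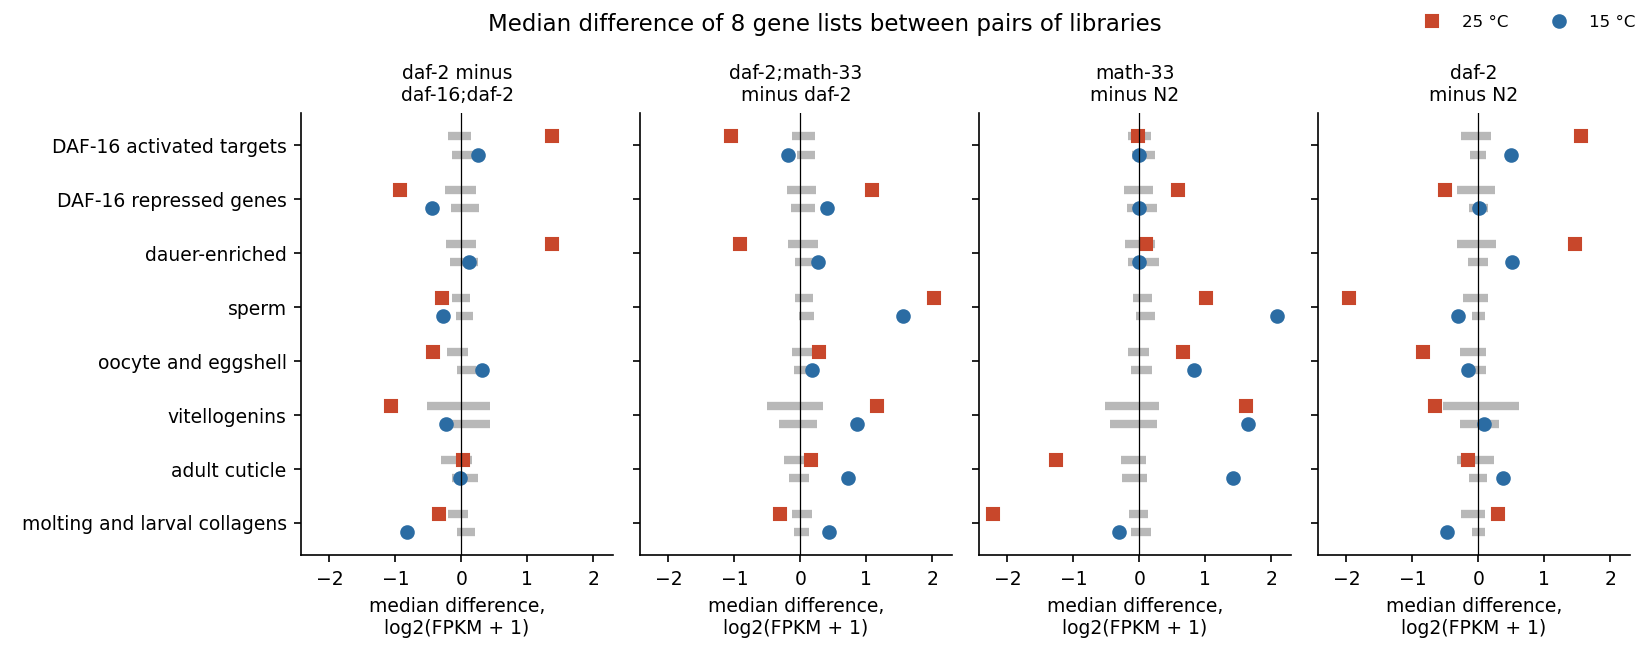
Median log2(FPKM + 1) difference of 8 gene lists in 4 comparisons, squares for the 25 °C libraries and circles for the 15 °C libraries, with grey bars for the central 95% of the medians of 10000 random lists matched on expression. DAF-16 activated targets stand at 1.37 for daf-2 minus daf-16;daf-2 and at -1.05 for daf-2;math-33 minus daf-2 at 25 °C, and sperm genes at 2.03 for daf-2;math-33 minus daf-2.

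The comparison of math-33 with N2 shows math-33 loss with an intact receptor. At 25 °C sod-3 was at 5.90 FPKM in math-33 and 5.15 in N2, a fold of 1.15 with an interval of 0.768 to 1.72. The levels of mtl-1 were 8.34-fold higher in math-33 at 25 °C (4.19 to 18.9) and 9.61-fold higher at 15 °C (3.39 to 37.5), and tts-1 stood at 328.6 against 34.4 FPKM (9.56-fold, 8.51 to 10.8). The lysozyme gene lys-7 went both ways, 1.73-fold higher in math-33 at 25 °C (1.49 to 2.01) and 2.24-fold lower at 15 °C (1.98 to 2.54). By the fixed rule, F08F3.9, now snpc-1.3, was at 33.05 against 1.11 FPKM. The noncoding RNA gene rpr-1 was at 17.4 FPKM and ins-19, an insulin-like peptide gene, at 8.38 FPKM, each against 0 in N2. At 15 °C the difference of rpr-1 was 0.959. The libraries hold polyadenylated RNA, so the rpr-1 values may not reflect the level of that RNA. The other 5 were 21ur genes, such as 21ur-13444, and include overlapping entries with equal values (21ur-10126, 21ur-372 and 21ur-10017). Lower in math-33 were K06G5.1 (6.82 against 221.8 FPKM), F57H12.6 (3.96 against 50.02) and the collagen gene col-156 (22.2 against 226.7), with 5 21ur genes, such as 21ur-12750. The DAF-16 activated targets as a group had medians of -0.02 at 25 °C and 0.00 at 15 °C, inside the random range, although their means were 0.29 and 0.28; 9 were higher and 1 lower at 25 °C. Repressed genes had a median of 0.58 at 25 °C and 0.00 at 15 °C, and they include the vitellogenins vit-2 and vit-5.

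Several lists tied to development also differed between math-33 and N2. At 25 °C 32 of 39 molting and larval collagen genes were lower in math-33 and 1 higher (median -2.21), with wrt-10 at 17.4 against 127.2 FPKM and noah-1, an apical matrix gene, at 25.4 against 165.0; at 15 °C the median was -0.31. Adult cuticle genes had a median of -1.27 at 25 °C, with col-143 at 883.7 against 211.2 FPKM and lon-3 at 31.5 against 231.5, and 1.42 at 15 °C. Sperm genes had medians of 1.01 and 2.08 at 25 and 15 °C, with fog-3, which specifies the sperm fate, at 21.3 against 2.12 FPKM. Vitellogenins had 1.61 and 1.65, and oocyte and eggshell genes 0.67 and 0.83. Xenobiotic detoxification genes had a median of -0.41 at 25 °C, the endoplasmic reticulum stress list -0.23, muscle -0.35, deubiquitylating enzymes 0.27 at 15 °C and the germline list 0.42 at 15 °C.

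In the limma contrast 56 genes rose in math-33 and 15 fell (2950 at an unadjusted p under 0.05), a share of 78.9% higher that was 67.9% after centring and 67.5% after quantile normalization. R09E10.2 rose by 3.41 (SE 0.38, adjusted p = 0.0205), H29C22.1 by 2.72 (SE 0.22, adjusted p = 0.0095) and T24B8.5, a PMK-1 pathway immune gene now called sysm-1, by 2.64 (SE 0.35, adjusted p = 0.0379), with 21ur-10477 and 21ur-5451 in the other places. K06G5.1 fell by 4.85 (SE 0.12, adjusted p = 1.86e-05), the collagen gene col-90 by 2.63 (adjusted p = 0.0404), K01D12.1 by 2.51 (adjusted p = 0.0447) and gpa-6, a G protein subunit gene, by 2.36 (adjusted p = 0.0211), with 21ur-14900 in the other place. Of the DAF-16 activated targets 0 passed, and 0 when adjusted over the list alone; their median was -0.13, their mean 0.29 and the camera direction lower (adjusted p = 0.89). Of the 5 vitellogenins 4 rose (5 when adjusted over the list alone), of the oocyte and eggshell genes 2 rose, perm-2 and perm-4 (24 when adjusted over the list alone), and of the 54 sperm genes 0 passed (44 rose when adjusted over the list alone). At 25 °C alone 845 genes were at least 1 log2 unit higher and 1151 lower, and at 15 °C 1843 and 448; the share higher at 15 °C, 80.4%, was 72.5% after centring and 65.8% after quantile normalization. The excess of higher genes in this contrast was not kept without the 15 °C library of math-33, in a fit that leaves that genotype with 1 library. The count of 71 was 3 without N2 at 15 °C, 185 without N2 at 25 °C, 4 without math-33 at 25 °C, 23 and 24 without daf-2;math-33 at 15 and 25 °C, and 34 without either daf-16;daf-2 library.

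The comparison of daf-2 with N2 concerns a partial loss of the receptor. A difference in stage between these strains cannot be told apart from it. At 25 °C mtl-1 was 192.0-fold higher in daf-2 (100.9 to 420.5), sod-3 29.7-fold (22.2 to 40.7) and lys-7 20.6-fold (18.2 to 23.3). Beside mtl-1, the genes with the largest differences included 5 collagen genes: col-36 (391.4 against 0.313 FPKM), col-37 (238.7 against 0.036), col-183 (164.6 against 0), col-158 (474.4 against 2.22) and col-84 (158.6 against 0.217). The other 2 of the 8 were the groundhog-like gene grl-23 (165.0 against 0.222 FPKM) and H39E23.3 (174.7 against 0.064). In daf-16;daf-2 col-37 was at 119.6 and 82.4 FPKM at 15 and 25 °C, and in daf-2 at 15 °C at 0.746. Lower in daf-2 was irg-5 (17.5 against 349.2 FPKM), with 7 21ur genes, such as 21ur-14945, and, among longer transcripts, msp-49 (8.57 against 111.4). DAF-16 activated targets had a median of 1.55 at 25 °C (26 higher, 0 lower) and 0.50 at 15 °C, and dauer-enriched genes 1.46 at 25 °C, with 17 of 22 higher. Sperm genes had a median of -1.96 at 25 °C (43 lower) and -0.30 at 15 °C, and oocyte and eggshell genes -0.84 at 25 °C. Innate immunity genes had a median of 0.67, neuronal genes 0.39, proteasome subunits -0.39 and ribosomal proteins -0.27 at 25 °C. The limma contrast called 0 genes (2189 at an unadjusted p under 0.05; 20 without N2 at 15 °C and 296 without daf-2 at 15 °C). Adjusted over the list alone, 16 DAF-16 activated targets rose, 8 dauer-enriched genes and 8 of carbohydrate metabolism rose, and 19 sperm genes fell, against 0 over all genes for each.

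Over both backgrounds, 542 genes were higher and 93 lower in the math-33(tm3561) strains (limma, 3449 at an unadjusted p under 0.05). The share of 85.4% higher was 74.6% after centring and 75.4% after quantile normalization. With 1 math-33 allele, this contrast does not set math-33 loss apart from differences in stage or other differences between the strains. K06G5.1 fell by 4.61 (SE 0.085, adjusted p = 2.31e-06), the F-box gene fbxa-192 by 2.41 (adjusted p = 0.00991), math-33 by 2.23 (adjusted p = 0.000361) and col-41 by 2.01 (adjusted p = 0.0323), with 21ur-15418 in the other place. The 5 largest increases were in 21ur genes, such as 21ur-12540 (3.21). Among them 21ur-10126, 21ur-372 and 21ur-10017 start at 13646506, 13646507 and 13646508 on chromosome IV. They overlap and had equal values in every library, so they are not separate observations. Among longer transcripts T24B8.5 rose by 2.84 (adjusted p = 0.00732), R09E10.2 by 2.65 (adjusted p = 0.0109) and ssp-19 by 2.496 (adjusted p = 0.0314). Of the 54 sperm genes 37 rose (49 when adjusted over the list alone; camera adjusted p = 2.54e-26, and adjusted p = 0.56 with an estimated correlation). All 5 vitellogenins rose, vit-2 by 1.37 (adjusted p = 0.00689) and vit-6 by 1.32 (adjusted p = 0.00892), and 5 oocyte and eggshell genes rose (19 when adjusted over the list alone), among them perm-2 by 1.69 (adjusted p = 0.0141) and perm-4 by 1.53 (adjusted p = 0.0152), eggshell permeability genes. Adult cuticle genes rose in 6 cases and fell in 2, innate immunity genes rose in 3 and fell in 3, and fat metabolism genes fell in 2. Of the DAF-16 activated targets lea-1 fell by 1.09 (adjusted p = 0.0478), a mean of opposite differences: lea-1 was higher in math-33 than in N2 by 0.65 and 1.1 at 15 and 25 °C, and lower in daf-2;math-33 than in daf-2 by 2.89 and 3.19. Of the repressed genes 4 rose, vit-2, vit-5, nuc-1 and dod-23.

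The count of 635 genes rested on the libraries used: it was 8 and 14 without daf-2;math-33 at 15 and 25 °C, 183 and 316 without math-33 at 15 and 25 °C, 161 without N2 at 15 °C, 298 and 91 without daf-2 at 15 and 25 °C, and 94 and 96 without daf-16;daf-2 at 15 and 25 °C. The excess of higher genes among those called was not kept without math-33 at 15 °C, a fit that leaves the math-33 genotype with 1 library. Counts at 1 log2 unit for daf-2;math-33 minus daf-2, which do not use the math-33 library at 15 °C, held more higher genes. They were 1764 higher and 825 lower at 25 °C, and 1416 and 317 at 15 °C. For math-33 minus N2 at 25 °C they went the other way, with 845 higher and 1151 lower. With 8 libraries and blocks for background and temperature, 44 genes rose and 5 fell. The interaction contrast, which asks whether the effect of math-33 loss differs between the backgrounds, called 0 genes (limma; 1390 at an unadjusted p under 0.05), and 3 without daf-2 at 25 °C. Across genes, the math-33 effects in the 2 backgrounds had r = 0.119 and rho = 0.112 at 25 °C, and r = 0.319 and rho = 0.29 at 15 °C; genes are not independent replicates. At 15 °C 737 genes were higher in both (162.2 from independent lists).

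**Figure D4:**
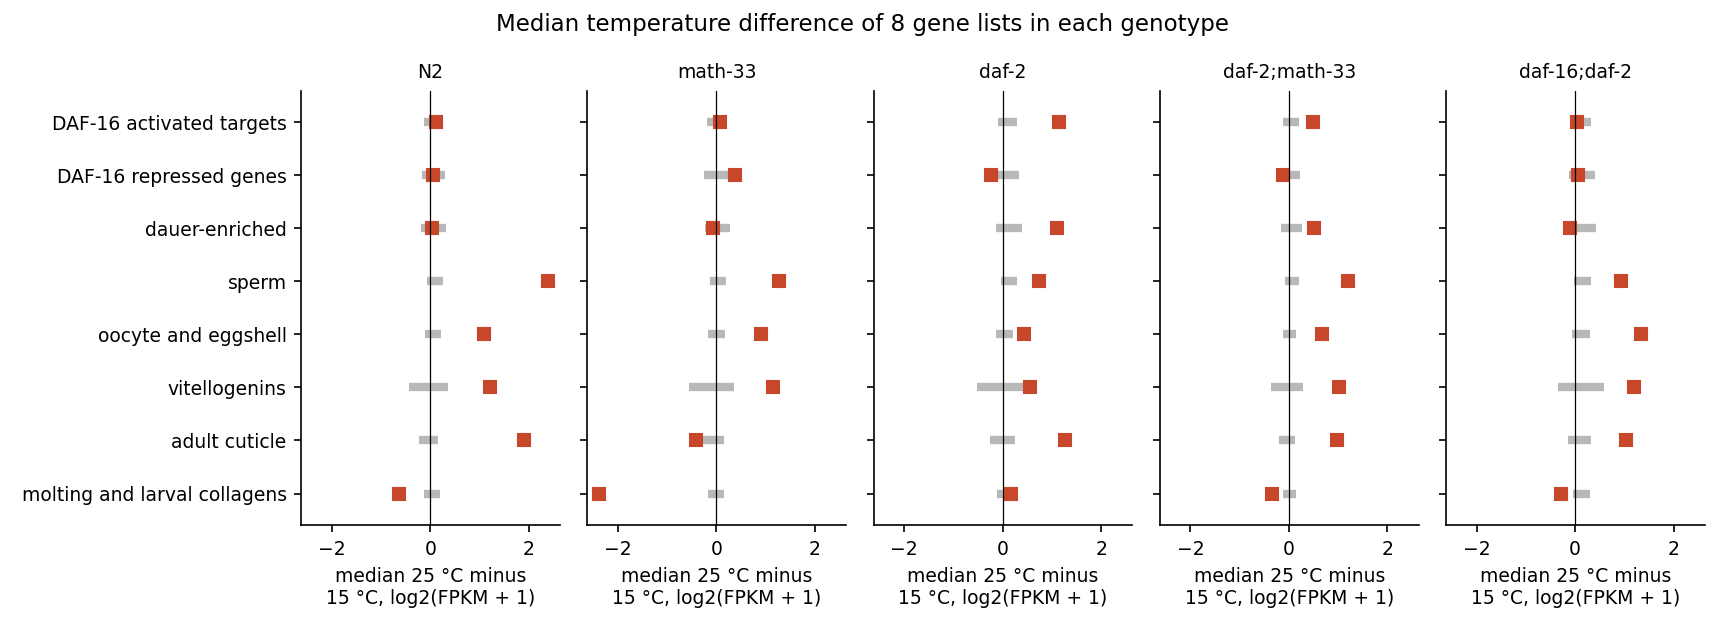
Median difference between 25 and 15 °C, log2(FPKM + 1), of 8 gene lists in each genotype (1 library per temperature), with grey bars for the central 95% of the medians of 10000 random lists matched on expression. DAF-16 activated targets stand at 1.14 in daf-2 and 0.04 in daf-16;daf-2, and molting and larval collagens at -2.38 in math-33.

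The shift to 25 °C was compared with 15 °C over the 5 genotypes. Direct responses to temperature and differences in stage cannot be told apart in this comparison. T24B8.5 rose by 2.79 (SE 0.22, limma adjusted p = 0.00327), the paralogs pud-4 and pud-3, named F15E11.12 and F15E11.15 in the table, by 3.196 (SE 0.56, adjusted p = 0.0137) and 3.02 (SE 0.52, adjusted p = 0.0133), and W04B5.1 by 2.72 (SE 0.20, adjusted p = 0.00289), with 21ur-15014 in the other place. The aspartyl protease gene asp-12, named F21F8.4 in the table, fell by 3.27 (SE 0.23, adjusted p = 0.00277), acdh-2, an acyl-CoA dehydrogenase gene, by 2.995 (SE 0.40, adjusted p = 0.0081), C37C3.10 by 2.40 (adjusted p = 0.00694) and nspc-18 by 2.26 (adjusted p = 0.00694), with 21ur-15627 in the other place; the desaturase gene fat-7 fell by 2.08 (SE 0.17, adjusted p = 0.00356). In all, 2346 genes rose and 753 fell (5713 at an unadjusted p under 0.05), a share of 75.7% higher that was 61.9% after centring and 50.2% after quantile normalization. Of the sperm genes 36 rose (43 when adjusted over the list alone), of the oocyte and eggshell genes 28 (30), of the vitellogenins 5 (5) and of the germline proliferation genes 12 (15), the numbers in brackets being adjusted over the list alone. Of the adult cuticle genes 6 rose and 1 fell, and of the molting and larval collagens 3 rose and 5 fell. Muscle genes fell in 10 cases, neuronal genes in 8 and intestinal genes in 6, with 0 rising. Heat-shock genes rose in 3 cases (sip-1, hsp-16.41 and hsp-16.2) and fell in 1, hsp-17, and of the endoplasmic reticulum stress genes xbp-1 and hsp-4 rose; 0 of the mitochondrial stress genes and 0 of the proteasome genes passed. Antioxidant enzymes rose in 4 cases and fell in 1, carbohydrate metabolism in 3 and 1, fat metabolism in 9 and 6, innate immunity in 7 and 6, xenobiotic detoxification in 1 and 6, the insulin/IGF pathway in 3 and 3, deubiquitylating enzymes in 4 and 1, and ribosomal proteins in 2 and 0. Camera placed the sperm list above other genes (adjusted p = 1.69e-12, and adjusted p = 0.56 with an estimated correlation).

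Of the DAF-16 activated targets 6 rose with temperature and 1 fell. By genotype, their median difference between 25 and 15 °C was 0.12 in N2, 0.07 in math-33, 1.14 in daf-2 (20 higher, 2 lower), 0.49 in daf-2;math-33 (7 higher, 1 lower) and 0.04 in daf-16;daf-2. Sperm genes had medians of 2.40 in N2, 1.27 in math-33, 0.74 in daf-2, 1.2 in daf-2;math-33 and 0.94 in daf-16;daf-2. Molting and larval collagens had a median of -2.38 in math-33, with 31 of 39 lower, against -0.63 in N2. The differences between genotypes in these medians were not tested, there being 1 library per temperature. The median of all genes was 0.12 in daf-2 and 0.13 in daf-16;daf-2. Quantile normalization moved the share of genes higher at 25 °C from 77.7 to 61.4% in N2, from 75.8 to 56.2% in daf-2, from 75.6 to 64.3% in daf-2;math-33 and from 70.9 to 54.3% in daf-16;daf-2 (59% after centring). The count of 3099 genes in the limma contrast was 1481 and 1453 without N2 at 15 and 25 °C, 821 and 824 without daf-2;math-33, and 1242 and 1211 without daf-16;daf-2.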

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

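The tests of a variant confined to K06G5.1, of a later stage of the math-33 libraries (in both forms), of counting error and of the daf-2 library at 25 °C, and both regressions for stage, were chosen only after the results were seen, as was the restriction to transcripts of at least 200 bases.

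Among transcripts of at least 200 bases, 2 genes differed by at least 1 log2 unit in one direction in both N2-background pairs and in the other direction in both daf-2-background pairs. The small heat-shock gene sip-1 was higher in math-33 than in N2 by 1.2 and 1.13 at 15 and 25 °C, and the difference between daf-2;math-33 and daf-2 was -2.74 and -2.58. F56A4.3 (chromosome V, 2453426 to 2456083) had differences of -1.07 and -1.42 between math-33 and N2, and of 3.82 and 2.79 between daf-2;math-33 and daf-2. F56A4.3 was at 25.847 and 25.955 FPKM in N2 and 18.231 and 20.689 in daf-2;math-33 at 15 and 25 °C. It was at 0.362 and 2.146 FPKM in daf-2 and at 0 and 0.214 in daf-16;daf-2. The low level was thus shared by both daf-2(e1370) strains without math-33(tm3561). For this gene, which is on the same chromosome as math-33, another difference between the strains was not set apart from math-33 loss. The interaction had an adjusted p of 0.195 in limma for both genes, so neither passed. Xenobiotic detoxification genes had list medians below 0 at both temperatures for math-33 against N2 and above 0 for daf-2;math-33 against daf-2; the difference of the means was 0.47 and was not tested.

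The file also holds transcripts without a gene name, which no comparison used. The transcript on chromosome IV starting at 13058294 was at 74.955 FPKM in math-33, 115.441 in daf-2 and 64.322 in daf-2;math-33 at 25 °C, above the 18.8 and 21.3 FPKM of N2 at 15 and 25 °C. It was at 12.33 and 22.7 FPKM in daf-16;daf-2. The transcript on chromosome III starting at 8962218 was at 136.938 FPKM in daf-2;math-33 at 25 °C against 0.034 and 0.039 in N2. It was also at 80.4 FPKM in daf-2;math-33 at 15 °C, 94.2 and 15.8 in daf-16;daf-2 at 15 and 25 °C, and 74.2 in daf-2 at 25 °C, but at 0.422 in daf-2 at 15 °C. No explanation was tested for these values.

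K06G5.1 was lower in all 4 math-33(tm3561) libraries than in their partners, with differences of -4.88 to -4.34. A lesion that also takes out its tested neighbours was argued against. The 10 nearest tested genes on chromosome X had a median math-33 effect of 0.088, from -0.13 to 0.38. The closest of them end at 14199702 on 1 side and start at 14238654 on the other, so a lesion inside that span would not be seen. A variant of K06G5.1 alone, carried by both math-33 strains, may be the source; the effect differed between the backgrounds by 0.49. That value is also what an effect of math-33 loss on K06G5.1 would give, so the 2 cannot be told apart with 1 math-33 allele.

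Genes that rose with math-33 loss over both backgrounds may reflect math-33 libraries taken at a later stage. The 542 genes had a median of 0.982 between 25 and 15 °C in daf-16;daf-2 (random lists 0.099 to 0.215), but the model that called them used both daf-16;daf-2 libraries for its spread. Without these libraries 44 genes were called higher, with a median of 1.273 (random lists -0.025 to 0.351), and the 1005 genes with an effect of at least 1 log2 unit had 0.902 (0.096 to 0.19). The math-33 library was the shallower one in 3 of the 4 pairs. Of the 542 genes 82.5% had a mean of 5 FPKM or more (65.3% of all tested genes). Binomial tests at each library's depth, combined over the 4 pairs with a Bonferroni limit over all tested genes, placed 95.9% beyond counting error. The genes were called in the same libraries and 1 pair can carry the combined test, so these shares cannot decide. A later check used math-33 and N2 at 25 °C, the pair with the deeper math-33 library. The 1335 genes used were at least 1 log2 unit higher in the mean of the other 3 pairs. Their median there was 0.344 (random lists 0.004 to 0.069). For these genes that argues against shallower sequencing of the math-33 libraries as the whole cause. A faster development of math-33 animals and a later harvest would look the same here, and both stay open. The difference between 25 and 15 °C also holds any direct response to temperature, so it is not a measure of stage alone.

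DAF-16 activated genes picked at 15 °C had a median of -0.29 between daf-2;math-33 and daf-2 at 25 °C, but 0.0 when picked at 2 log2 units (percentile 2.6, inside the central 95% of random lists). For the pick at 1 log2 unit the median was -0.014 at a pseudocount of 0.1 and -0.12 without a filter. It was -0.413 at a pseudocount of 5, -0.436 with a filter of 5 FPKM and -0.359 after centring. For the genes picked at 1 log2 unit, a regression on the temperature differences of N2 and daf-16;daf-2 left a median residual of -0.295 (random lists 0.016 to 0.108). It took up little of the difference (r squared 0.145), and the daf-16;daf-2 library at 15 °C was also used to pick the genes. The regression therefore cannot decide on a stage difference, which stays open. A daf-2 library at 25 °C that alone was out of place stays open: genes picked at 25 °C had a median of 0.033 at 15 °C, below random lists (0.119 to 0.184), but 16.37% were at least 1 log2 unit higher and 7.4% lower, and the median was -0.075 after centring, -0.092 after quantile normalization and 0.181 at a pseudocount of 0.1. A lower DAF-16 activity without math-33 may contribute, which stays a hypothesis with 1 library per group.

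For math-33 loss, with background and temperature as blocks, 1 of 32 splits of the 8 libraries gave as many genes: the real split gave 49 and the highest of the others 0, and 3 splits could not be fitted. Most of these splits mix the blocks. The splits that part all 4 pairs number 8, too few for a share under 0.05. For the temperature effect, 1 of 100 splits drawn from 126 gave as many genes: the real split gave 3099 and the highest of the others 19. The splits that part all 5 genotypes number 16, again too few for a share under 0.05; 14 of them were drawn, and the highest of these other than the real one gave 0.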

How the results depend on the processing

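The alternatives with transcripts of at least 200 bases and with either stage regression were chosen only after the results were seen. Unless stated otherwise, the cause was not tested. Counts of genes at least 1 log2 unit apart are given in a fixed order: daf-2 minus daf-16;daf-2, daf-2;math-33 minus daf-2, math-33 minus N2 and daf-2 minus N2, each at 25 and then 15 °C, then the temperature differences of N2, math-33, daf-2, daf-2;math-33 and daf-16;daf-2. The main counts were 1955, 1540, 2589, 1733, 1996, 2291, 2993, 928, 2753, 2150, 2477, 2154 and 2319. Medians of transferred genes are for activated genes picked at 15 and 25 °C, then repressed genes picked at 15 and 25 °C.

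A threshold of 2 log2 units gave 462, 300, 505, 285, 418, 500, 632, 179, 723, 353, 495, 216 and 352 by construction, and 1.5-fold gave 4498, 4140, 5010, 3867, 4440, 4627, 6055, 2712, 5428, 4948, 5339, 4471 and 5445. Genes picked at 2 log2 units had medians of 0.0 (percentile 2.6 of random lists), 0.059, 0.377 and 0.522. A pseudocount of 0.1 gave limma counts of 8 for daf-2;math-33 minus daf-2 and 4 for daf-2 minus N2, and 3089 and 2911 genes for daf-2 minus daf-16;daf-2, 3085 for daf-2;math-33 minus daf-2 at 15 °C, 3145 and 3510 for math-33 minus N2, 2230 for daf-2 minus N2 at 15 °C, and 3390, 3894 and 3794 for temperature in math-33, daf-2 and daf-16;daf-2; the medians were -0.014, 0.181, 0.365 and 0.458. A pseudocount of 5 gave limma counts of 5 and 1, genes apart of 772, 441, 1042, 430, 814, 847, 1216, 203, 1137, 878, 861, 735 and 680, and medians of -0.413, -0.024 (reversed) and, for the last, 0.304.

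Of the counts for daf-2;math-33 minus daf-2, 5 of 8 genes were higher at the first pseudocount and 3 of 5 at the second, against 0 of 2 in the main model. Without a filter limma called 1983 genes for temperature, 4 for daf-2;math-33 minus daf-2 and 106 for math-33 loss, and of 4 genes for daf-2 minus daf-16;daf-2 1 was higher and 3 lower, against 5 and 1 in the main model; the medians were -0.12, 0.0, 0.116 and 0.164. A filter of 5 FPKM gave 18 limma genes for daf-2;math-33 minus daf-2 (11 higher, 7 lower), and 1115, 905, 1684, 1111, 1328 (math-33 minus N2 at 25 °C), 479 (daf-2 minus N2 at 15 °C) and 1631 (temperature in daf-2) genes apart, from fewer genes tested; the medians were -0.436, 0.346 and 0.329, the second of the 4 not moving. Centring gave 12 limma genes for daf-2;math-33 minus daf-2 (6 higher, 6 lower) and medians of -0.359, -0.075 (reversed), 0.135 and 0.169. Quantile normalization gave 276 genes for math-33 loss and medians of -0.344, -0.092 (reversed), 0.082 and 0.092.

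With every transcript separately limma called 13 genes for daf-2 minus daf-16;daf-2 and 36 for daf-2;math-33 minus daf-2 (17 higher, 19 lower), with medians of -0.317 (activated, picked at 15 °C) and 0.306 (repressed, picked at 25 °C). Transcripts of at least 200 bases gave 18 limma genes for daf-2;math-33 minus daf-2 (12 higher, 6 lower), 7 for daf-2 minus N2, 503 genes apart for daf-2 minus N2 at 15 °C, medians of -0.43, 0.298 and 0.348 (the second of the 4 not moving), and a correlation between the math-33 effects at 15 °C of 0.424. A temperature term for the daf-2 strains gave 2 genes for daf-2 minus daf-16;daf-2, 260 for math-33 loss and 1 for the interaction. No trend gave 3, 7 (daf-2;math-33 minus daf-2) and 406 (math-33 loss). The 8-library blocked model gave 49 genes for math-33 loss. The second stage regression gave a median residual of -0.322. Of the set tests, 80 passed at the preset correlation, 0 with an estimated correlation and 0 with fry.

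Leaving out each library in turn gave 821 to 2299 genes for temperature, 0 to 169 for daf-2 minus daf-16;daf-2, 1 to 160 for daf-2;math-33 minus daf-2, 3 to 263 for math-33 minus N2, 0 to 296 for daf-2 minus N2, 8 to 801 for math-33 loss and 0 to 3 for the interaction; a lone library was assumed to vary like the others. The report gives the libraries. The remaining alternatives left 57 limma counts and 74 counts of genes apart within 1.5 times the main count. Depth limits values near 0: 1 read in a transcript of 1000 bases equals 0.0284 to 0.0397 FPKM.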

Other observations

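The test of the DAF-16 targets in the math-33 single mutant was chosen only after the result was seen.

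Collagen genes that were nearly silent in N2 followed neither temperature nor DAF-16 alone. In N2 and math-33 col-37 was at most 0.356 FPKM, col-2 at most 0.461 and col-40 at most 0.248. In daf-2 at 15 °C they stood at 0.746, 0.629 and 0.408 FPKM, and in daf-2 at 25 °C at 238.7, 141.4 and 87.9. In daf-2;math-33 they were at 166.2, 99.9 and 67.4 FPKM at 15 °C and at 349.8, 197.0 and 123.6 at 25 °C, and in daf-16;daf-2 at 119.6, 88.4 and 53.8 at 15 °C and 82.4, 53.2 and 33.7 at 25 °C. These genes were chosen after their values were seen.

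The lipid genes fat-7 and acdh-2 were low at 25 °C in each genotype. The desaturase gene fat-7 was at 4.75 to 8.95 FPKM at 15 °C and 0.215 to 0.966 at 25 °C. The acyl-CoA dehydrogenase gene acdh-2 was at 13.5 to 36.4 FPKM at 15 °C and at 2.64, 3.51, 0.147, 0.221 and 9.43 FPKM at 25 °C in N2, math-33, daf-2, daf-2;math-33 and daf-16;daf-2.

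A hypothesis was that math-33 loss with an intact receptor raises the DAF-16 activated targets as a group, since mtl-1 and tts-1 were higher in math-33 than in N2. The list median lay at percentiles 35.73 and 29.6 of random lists at 25 and 15 °C, inside the range of random lists. The members did not move alike: 9 were at least 1 log2 unit higher and 1 lower at 25 °C, 7 and 2 at 15 °C, and the means were 0.29 and 0.28. Genes picked from daf-2 against daf-16;daf-2 were also read in math-33 against N2 at the other temperature. Activated genes picked at 15 °C had a median of 0.125 at 25 °C (percentile 100), and those picked at 25 °C had 0 at 15 °C (percentile 0). Repressed genes picked at 15 °C had -0.108 at 25 °C (percentile 0), and those picked at 25 °C had 0.047 at 15 °C (percentile 13.11). The 2 temperatures differ, and with 1 library per group these values leave the hypothesis open.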
